A study of Homo sapiens with 6 samples.

How the data were processed

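Total RNA of 6 MCF-7 samples, 3 of the RCCD1 group and 3 of the Vector group, was extracted with TRIzol and made into Illumina libraries, per the labels' protocols. The deposited files hold raw read counts per gene, 1 file per library, with 60683 Ensembl genes and 5 summary lines each. The submitters' processing notes name fastp 0.23.0, STAR, HTSeq and DESeq2 and the builds GRCh38 and hg38, without a role or order. The strand setting, the annotation release and the read length are not given in the sources used here. The 5 summary lines name no gene and stayed out of library sizes and tests. Reads without a feature made up 48.6% to 49.4% of all lines, ambiguous reads 2.70% to 2.91% and reads without a unique position 3.71% to 4.16%, and reads on genes 43.8% to 44.8%.

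Counts assigned to genes were 9521771, 9645944 and 8810016 in Vector replicates 1, 2 and 3, and 9700986, 8300319 and 8111182 in RCCD1 replicates 1, 2 and 3. Symbols were found for 60370 gene IDs in the name table, and coordinates were taken from GENCODE release 29 (GRCh38), which lists 58496 of the IDs. Groups and replicate numbers were taken from the labels. Replicate pairs were compared by a chi-square test of their counts over genes, and every pair differed by more than sampling noise (chi-square per degree of freedom from 1.61 to 2.48). No pair looked like one library deposited again, and each library was entered as 1 replicate, which does not show that they are separate cultures.

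Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM factors, the filterByExpr rule (a minimum count of 10 and a minimum total of 15) and group as the only term. The p-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes, and their SD is over the 3 libraries of a group. The common biological coefficient of variation was 3.94%. Before the data were examined, 43 gene lists were fixed, and the 41 with at least 5 measured members were tested with limma 3.58.1's camera, with a preset correlation of 0.01, on log2 CPM with a prior count of 2. The p-values were adjusted over the lists. The count of called members is given over all tested genes and adjusted over the list alone. Shares of counts were compared by an exact two-sided permutation test over the 10 splits, whose smallest p is 0.1.

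Genes were named by a rule fixed before the data were examined. It took RCCD1, the 12 largest log2 fold changes in each direction among called protein-coding genes with a mean of at least 2 CPM and no overlap between groups, up to 4 called members of each list by smallest p (or 2 as values only), every mRNA encoded by mtDNA and the 3 genes with the smallest p in each direction.

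The scripts were tested on simulated data. Counts for RCCD1 against Vector were drawn for the real genes, with a change seeded in 200 of them, and 15934 genes passed the filter. The test recovered 81 of 93 genes changed 2-fold and 34 of 100 changed 1.25-fold, with 5 false calls (4.17% of calls), and camera called 0 of 40 unchanged lists of 30 genes. Each gene was drawn independently, so these lists do not test camera where genes vary together. In the data the estimated correlation was 0.71 for the mRNAs of mtDNA and 0.45 for cytosolic ribosomal proteins.

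The counting's use of strand was checked on 321 non-coding or antisense genes of which at least 90% of the exon bases lie within exons of a coding gene on the opposite strand. The median ratio of their counts to the counts expected if reads carried no strand and each was counted for the strand it happened to show was 1.57, and 88.8% of ratios were at least 0.1. Reads of a gene and of a partner on the opposite strand are therefore treated as not separable, and values of overlapping genes, of histone genes and of others with near-identical copies are uncertain to that extent.

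Alternatives fixed before the data were examined were other scalings (RLE size factors, library totals only, upper quartile, and a scaling without mtDNA-encoded genes), 2 other low-count filters, DESeq2 1.42.0, limma-voom, glmTreat, the replicate number as a block, each library left out in turn, a correction for GC content and length (both known for 98.9% of tested genes), camera with an estimated correlation and fry. A fit without genes in shifted chromosome segments was added after seeing the data. No sample or file was left out.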

Results

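RNA sequencing was used to compare MCF-7 cells, an established line derived from a human mammary adenocarcinoma that carries the estrogen receptor, after infection with a lentivirus for FLAG-tagged RCCD1 or with a control vector. RCCD1 is an RCC1-domain protein known as a partner of the histone demethylase KDM8. The series title places RCCD1 in mitochondria and concerns the dynamics of mtDNA and the state of mitochondria, and the single comparison asks how the transcriptome differs when RCCD1 is raised. The RCCD1 group and the Vector group held 3 libraries each. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Counts assigned to genes ranged from 8111182 to 9700986 per library, and 24036 to 24915 genes had at least a count. Every pair of replicates of a group differed by more than sampling noise, and the lowest correlation of log2 CPM within a group was 0.9896.

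RCCD1 itself was 30.9-fold higher in the RCCD1 group. Its level was 45.9 ± 4.5 CPM in Vector cells and 1414 ± 15.4 CPM in RCCD1 cells (mean ± SD, n = 3 each), from 387 to 432 counts and from 11637 to 13840 counts per library. The log2 fold change was 4.95 ± 0.04 (SE), with an edgeR adjusted p of 2.0e-68. The gene (ENSG00000166965) lies on the plus strand of chromosome 15 at 90954870 to 90963125 (GRCh38), and 79 of its exon bases overlap RCCD1-AS1 on the opposite strand. Counts do not separate the transcript of the lentivirus from that of the cells' own gene.

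**Figure D1:**
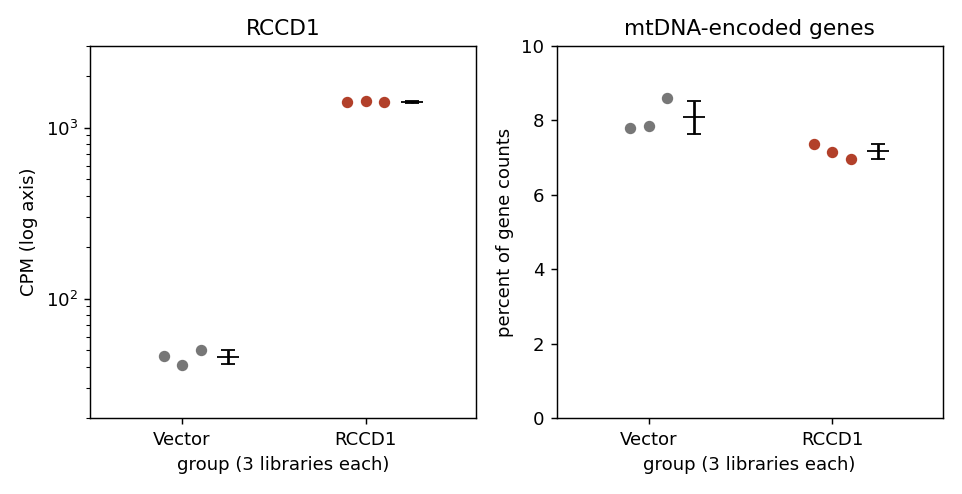
Left, RCCD1 in CPM (log axis), and right, the percent of gene counts on genes encoded by mtDNA, for the 3 Vector and the 3 RCCD1 libraries; points are libraries, and the bars beside them are the mean ± SD. RCCD1 averaged 45.9 CPM in Vector and 1414 CPM in RCCD1 libraries, and the mtDNA share averaged 8.08% and 7.16%.

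Most mRNAs encoded by mtDNA were lower in RCCD1 cells. Of the 13, 11 fell and 2 were called higher, over all genes as well as adjusted over the list alone, with a median log2 fold change of -0.31. MT-CO3, a subunit of cytochrome c oxidase, fell from 6736 ± 176 to 4142 ± 43.9 CPM, a log2 fold change of -0.70 ± 0.02 (SE). MT-ND1 of complex I fell by 0.61 on the log2 scale, and the ATP synthase subunits MT-ATP8 and MT-ATP6 by 0.57 and 0.54. MT-ND2 changed by -0.41, MT-ND3 by -0.37, MT-CO1 by -0.31, MT-CYB by -0.24, MT-ND4L by -0.20, MT-ND4 by -0.18 and MT-CO2 by -0.14. MT-ND6, the one mRNA transcribed from the opposite strand of mtDNA to the others, was higher by 0.19 ± 0.03 (SE), at 3272 ± 245 CPM in Vector and 3745 ± 51.3 CPM in RCCD1 cells. Reads of RNA from the strand opposite MT-ND6 cannot be told apart from its own in these counts. MT-ND5 had a log2 fold change of 0.11 ± 0.03 (SE), but its CPM values overlapped between the groups.

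Under DESeq2 the call of MT-ND5 (adjusted p = 0.36) and that of MT-ND4 (adjusted p = 0.095) were lost. With a library left out MT-ND5 ran from 0.06 to 0.18 and MT-ND4 from -0.22 to -0.10. The counts of 11 lower and 2 higher were the same under TMM, RLE, library totals and the upper quartile. The set of 13 moved down in camera, a test of a list against all other genes (adjusted p = 5.1e-04), but these genes vary together between replicates, and the adjusted p was 0.48 with an estimated correlation. The share of counts on all genes encoded by mtDNA was 8.08% ± 0.45 (SD, n = 3) in Vector and 7.16% ± 0.20 (SD, n = 3) in RCCD1 libraries, with no overlap and an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give. The share on the ribosomal RNAs of mtDNA was 1.01% and 0.997% (exact permutation p = 0.7).

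**Figure D2:**
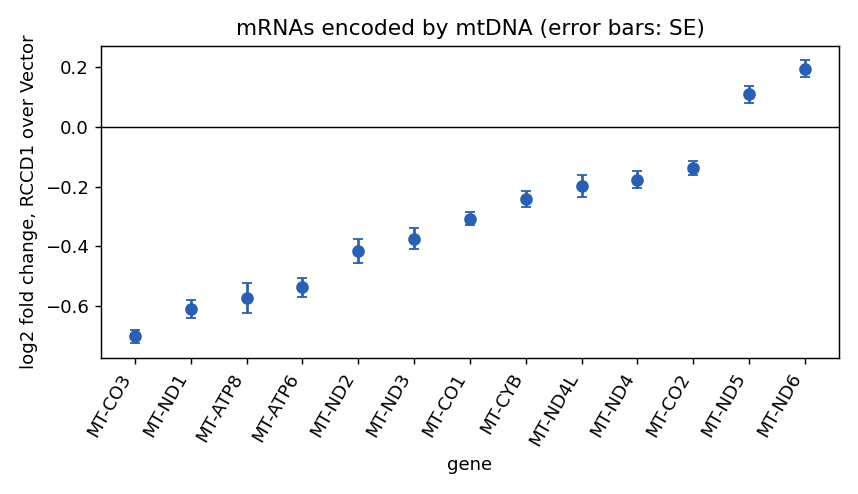
Log2 fold change, RCCD1 over Vector, of the 13 mRNAs encoded by mtDNA, from 3 libraries per group; points are edgeR estimates and error bars their standard errors. Values run from -0.70 for MT-CO3 to 0.19 for MT-ND6, and MT-ND5 and MT-ND6 are the points above 0, MT-ND5 without a call under DESeq2.

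Several lists of nuclear genes for mitochondrial proteins passed camera on the lower side. Among 75 mitochondrial ribosomal proteins 22 fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 0.0024; adjusted p = 0.25 with an estimated correlation). MRPL17 fell by 0.48 and MRPL16 by 0.42 on the log2 scale. In the list of import and cristae proteins 9 of 29 fell and 1 rose (13 and 1 adjusted over the list alone; camera adjusted p = 0.024; adjusted p = 0.23 with an estimated correlation), with the prohibitin PHB2 at -0.35 ± 0.05 (SE) and the import pore TOMM40 at -0.29 ± 0.04 (SE). Of 25 genes of the tricarboxylic acid cycle and pyruvate entry 13 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0028; adjusted p = 0.13 with an estimated correlation). SUCLG2 fell by 0.52 and the fumarase gene FH by 0.41. Under library totals the counts of lower genes were smaller, with 11 lower and 4 higher for ribosomal proteins, 8 and 1 for import and cristae and 7 and 0 for the tricarboxylic acid cycle. The medians were then -0.06, -0.07 and -0.06.

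Nuclear subunits of complex I (12 of 35 lower, 1 higher; 13 and 1 adjusted over the list alone) lay just outside the camera threshold at an adjusted p of 0.0504. With a library left out this p ran from 0.0034 (without Vector replicate 3) to 0.179 (without Vector replicate 1), and over all alternatives to 0.55 with an estimated correlation. Subunits of complexes II to IV (7 lower and 1 higher of 26) and of ATP synthase (8 lower and 1 higher of 18) did not pass (camera adjusted p = 0.47 and 0.089), with the same counts adjusted over the list alone. Without Vector replicate 3 the p of ATP synthase was 0.024, in a range up to 0.237 with a library left out. Under library totals complex I had 6 lower and 2 higher, complexes II to IV 4 and 4, with a median above 0, and ATP synthase 5 and 2. Cytochrome c, CYCS, fell from 188 ± 17.8 to 144 ± 3.9 CPM (SD, n = 3 each), and ATP5F1B fell by 0.27 on the log2 scale. Of 35 genes for mtDNA maintenance and transcription 6 fell and 3 rose, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.47). Its balance turned round under library totals, with 2 lower and 3 higher and a median of 0.03, and was 3 and 3 under the upper quartile. SSBP1, which binds single-stranded mtDNA, was at -0.25 ± 0.05 (SE), the nuclease DNA2 at -0.42 ± 0.11 (SE) and the mitochondrial RNA polymerase POLRMT at 0.22 ± 0.06 (SE). Mitochondrial RNA processing (4 lower, 1 higher of 19), fission and fusion (3 lower, 6 higher of 24) and mitochondrial chaperones and proteases (4 lower, 5 higher of 18) did not pass, with camera adjusted p of 0.23, 0.65 and 0.93 and the same counts adjusted over the list alone. Under library totals they had 1 lower and 1 higher, 1 and 8, and 3 and 7. In the last of these HSPD1, the mitochondrial HSP60, rose by 0.27 ± 0.03 (SE) and TRAP1 had a log2 fold change of -0.31 ± 0.04 (SE).

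Genes of the integrated stress response rose together. Of 32 measured members 28 rose and 1 fell, also adjusted over the list alone, with a median log2 fold change of 0.52 (camera adjusted p = 9.8e-13; adjusted p = 0.036 with an estimated correlation). The cystine transporter SLC7A11 rose from 13.1 ± 1.3 to 49.7 ± 3.3 CPM (SD, n = 3 each), a log2 fold change of 1.92 ± 0.10 (SE). The amino acid transporter subunits SLC7A5 and SLC3A2 rose by 0.97 and 0.71, and the alanyl-tRNA synthetase AARS1 by 0.59. Among 27 genes of mitophagy and autophagy 11 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 1.0e-04; adjusted p = 0.060 with an estimated correlation). The LC3 family members GABARAPL1 and MAP1LC3B rose by 1.93 and 0.60, and the cargo receptors SQSTM1 and OPTN by 0.89 and 0.71. SQSTM1 shares 1582 exon bases with MRNIP on the other strand, and lies in a chromosome block, a run of neighbouring genes that moved together, for which copy number is open. Of 13 cytosolic heat shock genes 9 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 8.8e-05; adjusted p = 0.060 with an estimated correlation). HSP90AA1 rose from 2296 ± 68.6 to 3866 ± 11.4 CPM, and HSPH1 rose by 0.56 on the log2 scale. Of 26 p53 targets 9 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 7.9e-04; adjusted p = 0.072 with an estimated correlation), among them TP53INP1 at 0.81 ± 0.06 (SE) and GDF15, which is also in the stress response list, at 0.52 ± 0.07 (SE). Under library totals 14 p53 targets were higher and 1 lower, and under the upper quartile 12 and 1.

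Genes of DNA replication fell. In the list of S-phase and DNA replication 40 of 42 members fell and 0 rose, also adjusted over the list alone, with a median of -0.55 (camera adjusted p = 7.2e-21; adjusted p = 0.013 with an estimated correlation). Subunits of the replicative helicase were among them. MCM3 fell from 266 ± 9.9 to 143 ± 5.5 CPM (SD, n = 3 each), and MCM6, MCM2 and MCM7 fell by 0.83, 0.66 and 0.54 on the log2 scale. Of 41 genes of mitosis and G2/M 29 fell and 0 rose (30 and 0 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 3.7e-10; adjusted p = 0.060 with an estimated correlation). The proliferation marker MKI67 changed by -0.39 ± 0.04 (SE), TOP2A by -0.48 ± 0.04 (SE) and the kinase gene PBK by -0.80 ± 0.07 (SE). Replication-dependent histone genes moved the other way. Of 24 measured genes 12 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 0.60 (camera adjusted p = 2.3e-07; adjusted p = 0.036 with an estimated correlation). H2BC5 rose from 16.2 ± 0.20 to 34.3 ± 4.0 CPM, and H4C8, H2AC11 and H2AC6 rose by 0.92, 0.85 and 0.70 on the log2 scale. Most mRNAs of these histones lack a poly(A) tail, and the sources used here do not say whether the RNA was selected by that tail. RN7SL1, another RNA without the tail, had a log2 fold change of 1.28 ± 0.20 (SE), but its values overlapped between the groups, and it was 0.35 without RCCD1 replicate 3 and not called by DESeq2 (adjusted p = 0.19). Histone genes have near-identical copies, so the split of reads between single members is uncertain.

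Estrogen response genes fell. Of 34 members 31 fell and 3 rose, also adjusted over the list alone, with a median of -0.67 (camera adjusted p = 3.7e-16; adjusted p = 0.022 with an estimated correlation). The progesterone receptor gene PGR fell from 56.7 ± 1.4 to 11.6 ± 1.7 CPM (SD, n = 3 each), a log2 fold change of -2.28 ± 0.10 (SE). The chemokine gene CXCL12 fell by 2.33, the kinase inhibitor gene PKIB by 1.74, the receptor kinase gene RET by 1.51 and the transcription factor gene XBP1 by 1.29 on the log2 scale. The estrogen receptor gene ESR1 was at 288 ± 7.8 CPM in Vector and 178 ± 1.7 CPM in RCCD1 cells, a log2 fold change of -0.69 ± 0.04 (SE). Genes of luminal epithelial identity, a list that shares ESR1 with this one, went both ways. Of 25 members 11 fell and 7 rose (11 and 8 adjusted over the list alone), with a median of -0.02 that was above 0 under library totals and under the upper quartile (camera adjusted p = 0.13, and 0.028 without a low-count filter). AGR2 and AGR3, neighbouring genes for secretory pathway proteins, changed by -1.93 and -3.27, and MUC1 by -0.89.

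**Figure D3:**
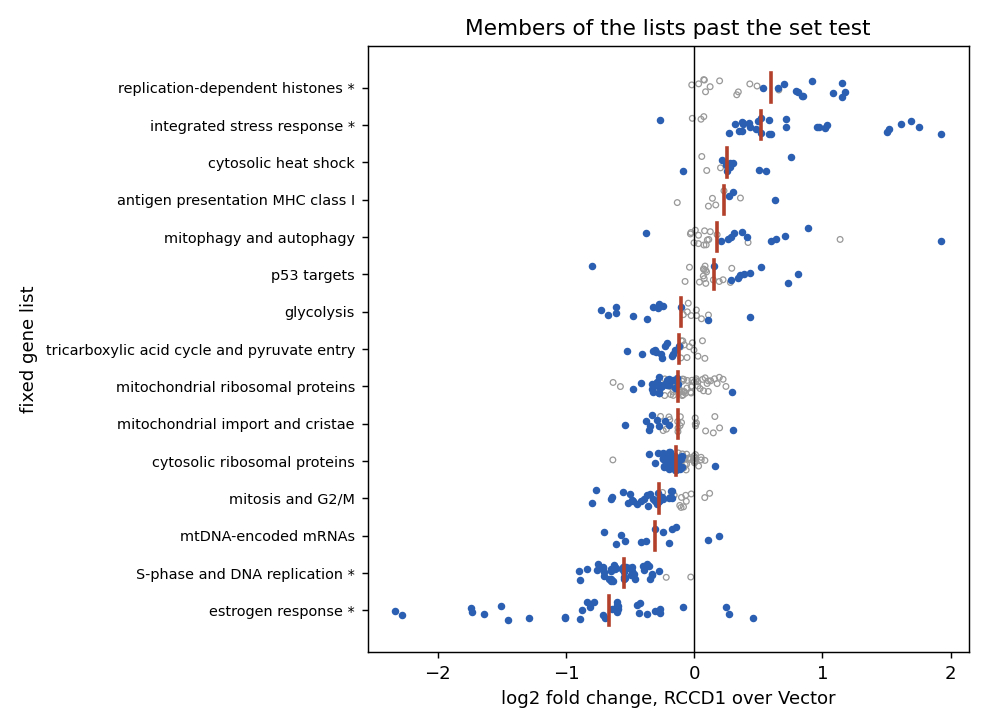
Log2 fold change, RCCD1 over Vector, of each measured member of the 15 fixed lists past the camera test; filled points passed an adjusted p of 0.05 in edgeR, open points did not, and red bars are list medians. The 4 lists marked with an asterisk also passed with an estimated correlation, and their medians are 0.60 and 0.52 for histones and the stress response and -0.55 and -0.67 for DNA replication and the estrogen response.

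Of 21 glycolysis genes 11 fell and 2 rose (12 and 2 adjusted over the list alone; camera adjusted p = 0.0087; adjusted p = 0.31 with an estimated correlation). LDHA fell from 644 ± 9.4 to 422 ± 11.6 CPM, and the glucose transporter gene SLC2A1 fell by 0.67 and HK1 by 0.48 on the log2 scale. Cytosolic ribosomal protein genes fell by little. Of 77 members 51 fell and 1 rose (52 and 1 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 8.2e-06; adjusted p = 0.54 with an estimated correlation), and RPL29, which lies in a lower block of chromosome 3, and RPL7A were at -0.35 ± 0.04 and -0.31 ± 0.03 (SE). Under library totals the median was -0.08, with 33 lower and 4 higher, and glycolysis had 10 lower and 4 higher. Of 9 genes for antigen presentation by MHC class I 3 rose and 0 fell, also adjusted over the list alone, and 5 and 0 under library totals and under the upper quartile (camera adjusted p = 0.029; adjusted p = 0.23 with an estimated correlation). TAP1 rose by 0.63 ± 0.09 (SE), and without RCCD1 replicate 2 the camera adjusted p of the list was 0.099, the highest of a range from 0.015 with a library left out. NRF2 antioxidant genes (13 higher and 6 lower of 24, also adjusted over the list alone) had a camera adjusted p of 0.0503, which ran from 0.033 (without Vector replicate 2) to 0.090 with a library left out.

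Markers of other cell types were included in the fixed lists. Of the leukocyte and endothelial markers 2 each were measured, too few for the set test. Of the leukocyte markers 1 was called higher and 0 lower (1 and 1 adjusted over the list alone), and of the endothelial markers none was called in either adjustment. ITGAM was at 7.68 ± 1.6 CPM in Vector and 12.5 ± 1.9 CPM in RCCD1 cells, and the endothelial markers EMCN and ESAM, neither past the test, had log2 fold changes of 0.16 ± 0.24 and 0.08 ± 0.32 (SE). Of 9 fibroblast markers 2 rose and 3 fell, and of 12 basal and mesenchymal markers 3 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.24 and 0.68). TAGLN and ACTA2, genes of contractile proteins, fell by 0.78 and 1.33 on the log2 scale, and the basal keratin gene KRT17 fell by 1.61. The basal list had a median of 0.16 but a mean of -0.15, and its test pointed down.

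Over the whole transcriptome, 5540 of 16191 tested genes (34.2%) had an edgeR adjusted p under 0.05, 2580 of them higher and 2960 lower in RCCD1 cells. Most differences were small. A filter of at least 2-fold after the test left 571 genes, 356 higher and 215 lower, while the glmTreat test against a 2-fold change called 96. For 43.6% of tested genes the groups did not overlap in CPM, against 10% expected by chance. Scaling by library totals moved the median of all genes by less than 0.1 but gave 3515 higher and 2155 lower, 62.0% higher against 46.6%, so the balance of directions is not fixed by these data.

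Among called protein-coding genes with a mean of at least 2 CPM and no overlap between groups, the largest rises after RCCD1 were those of TDRD1, LRATD1, NDUFA4L2, MMP16, FBXW10B and SNTB1. LRATD1 rose by 3.26 ± 0.18 (SE) on the log2 scale, and NDUFA4L2, a paralogue of a respiratory chain subunit, from 0.618 ± 0.14 to 4.46 ± 0.22 CPM. The matrix metalloprotease gene MMP16 rose by 2.72, PRKD1 by 2.44 and DHRS3, a retinaldehyde reductase gene, by 2.41 on the log2 scale. CACNG6, PRICKLE1 and TMEM59L followed at 2.21, 2.16 and 2.16. Some of these rises rest on few reads over all libraries, such as 108 counts for PRKD1, 118 for SNTB1 and 136 for NDUFA4L2. With a library left out SNTB1 ran from 1.99 to 3.22 and TDRD1 from 3.54 to 4.55, against 3.22 to 3.28 for LRATD1. Among the same genes the largest drop was that of the kallikrein gene KLK11, from 17.8 ± 1.5 to 0.890 ± 0.20 CPM, a log2 fold change of -4.28 ± 0.22 (SE). RAMP3, a receptor activity-modifying protein gene, fell by 3.64 and the growth factor binding protein gene IGFBP5 by 2.97. ACTG2, TMEM26, BMPER and IGSF1 fell by 2.67, 2.59, 2.58 and 2.52, and RBM24 and LOXL4 by 2.30 and 2.09. By smallest p, the non-coding RNA XIST of the X inactivation centre and its antisense partner TSIX followed RCCD1 among the rises. XIST was at 11.5 ± 2.4 CPM in Vector and 150.0 ± 5.2 CPM in RCCD1 cells (SD, n = 3 each), with a log2 fold change of 3.72 ± 0.08 (SE), and TSIX had one of 3.44 ± 0.10 (SE). These genes share 7498 exon bases on opposite strands, and their reads cannot be assigned to a strand from these counts. Among drops, the protease gene PRSS23 had the smallest p, falling from 1113 ± 40.1 to 316 ± 2.6 CPM.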

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

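Shares of reads and counts outside the gene comparison are reported here as values. Reads without a unique position made up 4.05% ± 0.13 (SD, n = 3) of all lines in RCCD1 libraries and 3.74% ± 0.03 (SD, n = 3) in Vector libraries, with no overlap (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries can give). Genes left out by the low-count filter took 0.332% ± 0.014 (SD, n = 3) of gene counts in RCCD1 libraries and 0.270% ± 0.004 (SD, n = 3) in Vector libraries, also with no overlap (exact two-sided permutation p = 0.1). Ambiguous reads (2.87% to 2.91% in Vector, 2.70% to 2.72% in RCCD1 libraries) and the number of genes detected (24036 to 24130 and 24544 to 24915) did not overlap either, with the same exact permutation p of 0.1 each.

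Of the tests in the next 3 paragraphs, those of scaling and of luminal genes for the estrogen list, those for mtDNA, and that of the share of genes on one side for blocks were chosen after the result was seen.

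The drop of the estrogen response list was set against 3 other explanations. The highest median log2 fold change of the list over TMM, RLE, library totals and the upper quartile was -0.60, so the choice among these scalings does not account for it. These scalings lie close together, with a median of all genes from 0.007 (TMM) to 0.068 (library totals). The test could therefore hardly have come out otherwise. Of 24 luminal genes outside the list, 21 lay above the list's median by more than 2 standard errors. This argues against a drop shared by luminal genes, the form that a lower share of luminal cells was taken to have. MCF-7 is a single line, and the test does not reach a difference between the cell populations that came before RCCD1 was raised. Such a difference was not tested. The median over members of the log2 fold change of their 20 expressed neighbours on each side was -0.026, which argues against copy number of their neighbourhoods. A response to raised RCCD1 stays a hypothesis, since only the group separates the libraries and no test here isolates it.

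The 11 lower mRNAs of mtDNA were set against scaling, a single library and the counting of strand. At the least, 11 of the 13 were called lower over TMM, RLE, library totals and the upper quartile, which lie close together. Without Vector replicate 3, the library with the highest mtDNA share, 11 were called lower. MT-ND6 was higher by 0.19, beyond 2 standard errors, but opposite-strand reads may add to its counts, so it does not decide on an equal drop. Among the 11 lower mRNAs MT-CO3 was at -0.70 (-0.71 to -0.68 with a library left out) and MT-CO2 at -0.14 (-0.16 to -0.12). An equal drop of all 13 is therefore not what the counts show. The number of mtDNA copies was not measured, and these values do not decide on it. Whether reads from the strand opposite MT-ND6 could produce its rise cannot be told apart. The strand setting is not given, and the check of 321 opposite-strand genes gave counts like those of reads without strand (median ratio 1.57). MT-ND6 exceeded MT-ND5 by 0.085 ± 0.040 (SE), just past the bound of 2 standard errors set for this test. That bound does not decide, because the annotated genes share 0 bases and RNA opposite MT-ND6 has no count of its own.

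Neighbouring genes shifted together in 9 chromosome blocks of 510 genes, found as windows of 40 expressed genes whose median passed the limit of 0.199 from 1000 shuffles. The largest lay on chromosome 3 at 48625723 to 66038834 (120 genes, median log2 fold change -0.21), and 2 lay on chromosome 15, with RCCD1 inside the block from 90233808 to 101525202 (median 0.26); 3 more lay on chromosome 19. After a correction for GC content and length 21 windows passed a new limit of 0.197, but they were not matched to the first ones. That windows still passed argues against this bias as the only source of such shifts. All 9 blocks kept their direction, but they were picked for large shifts, so a kept direction adds little. Some medians shrank, as on chromosome 17 (0.18 to 0.13), and others grew, as on chromosome 3 (-0.21 to -0.23), so the bias may account for part of some blocks. For the blocks on chromosome 19, 203 zinc-finger genes on other chromosomes had a median of 0.048 (one-sided permutation p = 0.0011), just under the bound of 0.05 set beforehand, against 0.204 for 163 on chromosome 19, so a family-wide shift, smaller elsewhere, stays open. A copy-number difference between the cell populations also cannot be told apart, since the share of genes on a block's side (median 77.5%, against 79.9% for a uniform shift) comes from blocks picked for it. The shuffles treated genes as independent, although opposite-strand neighbours may share reads. Antisense partners of P4HB and ARHGDIA, for example, are among the block genes. The shuffled limit may therefore be too low, and how far shared reads add to the blocks was not tested.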

How the results depend on the processing

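The count of changed genes ranged from 4544 (DESeq2) to 5670 (library totals only) over the alternatives other than leaving out a library, and from 4681 to 5116 with a library left out. The fit without genes in shifted blocks, chosen after seeing the data, gave 5271. The numbers did not pair the samples (correlations of same-numbered deviations 0.025, 0.0035 and 0.0054), and the replicate block gave 5453. Under the block complex I passed camera (adjusted p = 0.046), SNHG1 lost its call (0.052), and no other call of a reported list or named gene changed. With the replicate block and the correction for GC content and length together, 5412 genes were called.

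The 571 genes at least 2-fold changed became 96 under glmTreat, by its construction a stricter question. The 15 lists past camera became 4 with an estimated correlation and 29 under fry, which does not compare a list with other genes. For the mRNAs of mtDNA as a set the adjusted p with an estimated correlation was 0.48. Of 3503 alternative values of named genes, 3463 kept their direction and side of the threshold, 37 lost the call and 3 reversed. The 3 reversals were in the uncalled EMCN (-0.019 to 0.32 with a library left out) and ESAM (-0.28 to 0.38).

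All other reversals were in lists not past camera, and the cause was not tested. The ER chaperones pointed down under fry (adjusted p = 0.022) and without a low-count filter (0.92). The list of RCCD1-KDM8 and H3K36 methylation did so under fry (0.96), without a filter (0.92), with the GC correction (0.68) and with that and the block (0.81). Mitochondrial chaperones did so without a filter (0.91), with the GC correction (0.92) and with that and the block (0.93). Without a filter, detoxification of reactive oxygen (0.92) and cholesterol biosynthesis (0.82) pointed down and nuclear-retained RNAs up (0.92). Nuclear-retained RNAs also pointed up under the block (0.95) and under the block with the GC correction (0.90), and immediate early genes under the block (0.99). Targets of the aryl hydrocarbon receptor pointed down without genes in shifted blocks (0.83).
With a library left out, lists that changed direction had camera adjusted p from 0.853 to 0.979 (mitochondrial chaperones), 0.835 to 0.966 (cholesterol biosynthesis), 0.83 to 0.982 (RCCD1-KDM8 and H3K36 methylation), 0.751 to 0.966 (nuclear-retained RNAs), 0.532 to 0.982 (aryl hydrocarbon receptor targets) and 0.776 to 0.982 (immediate early genes).
Small changes were called less often in simulated data, where depth and number of libraries were not varied. There 81 of 93 genes changed 2-fold were recovered, against 34 of 100 in the class of smaller change. A change was seeded in 200 genes, while 34.2% of tested genes were called in the data, so these shares may not carry over.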

Other observations

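The tests of tRNA synthetases and of retinoid genes were set before their results were seen, although the patterns they follow up were noticed in the data; the comparison with other splits was written down after its result was seen.

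Several other fixed lists had members that moved both ways and did not pass camera. Of 20 endoplasmic reticulum chaperone genes 5 rose and 4 fell, and under library totals 9 and 4 (camera adjusted p = 0.72), with HERPUD1 at 0.60 ± 0.10 and XBP1 at -1.29 ± 0.03 (SE). Of 21 hypoxia response genes 9 rose and 5 fell (10 and 5 adjusted over the list alone, 11 and 3 under library totals; camera adjusted p = 0.065, from 0.036 without RCCD1 replicate 1 to 0.099 with other libraries left out), with P4HA2 at 1.43 ± 0.08 and VEGFA at 0.60 ± 0.05 (SE). The lowest member of the hypoxia list was SLC2A1 at -0.67. In serine, glycine and folate metabolism 8 of 15 rose and 4 fell (camera adjusted p = 0.26). PHGDH, the first enzyme of serine synthesis, and MTHFD2 rose by 1.04 and 0.43, while MTHFD1 fell by 0.57 on the log2 scale. PHGDH and MTHFD2, like VEGFA of the hypoxia list, are also in the stress response list, so their rises are not separate findings. Detoxification of reactive oxygen (5 higher and 4 lower of 17, 5 and 2 under library totals, camera adjusted p = 0.92) included the peroxidase genes GPX3 at 1.83 ± 0.11 and PRDX3 at -0.42 ± 0.05 (SE). Of 26 apoptosis regulators 8 rose and 5 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.078), with BMF at 1.08 ± 0.14 (SE).

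Of 24 interferon-stimulated genes 7 rose and 3 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.71), with ISG15 at 0.47 ± 0.09 and OAS3 at -0.51 ± 0.09 (SE). Of 8 genes for sensing of cytosolic DNA and RNA 3 rose and 0 fell (camera adjusted p = 0.17), and MAVS was at 0.26 ± 0.04 (SE). Of 14 NF-kB targets 2 rose and 5 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.61), with NFKB2 at 0.82 ± 0.06 (SE). TNFAIP2, BCL3 and NFKBIA of this list were at -0.59, -0.37 and -0.31. Immediate early genes (9 higher and 7 lower of 29; 10 and 9 adjusted over the list alone) and the list of RCCD1-KDM8 and H3K36 methylation (2 higher and 3 lower of 12) had a camera adjusted p of 0.93 each. The balance of the latter depended on scaling, with 4 higher and 1 lower under library totals and 3 and 3 under the upper quartile. Fatty acid oxidation (3 higher and 2 lower of 22), fatty acid synthesis (3 and 2 of 15) and cholesterol biosynthesis (5 and 6 of 25) had camera adjusted p of 0.71, 0.47 and 0.94, and under library totals they had 5 higher and 2 lower, 6 and 1, and 5 and 3, and under the upper quartile 5 and 2, 6 and 1, and 5 and 4. Targets of the aryl hydrocarbon receptor (3 higher and 2 lower of 9) and nuclear-retained RNAs (2 and 2 of 6) had 0.93 each. For the lists of this part with no other count given, the count adjusted over the list alone was the same. The direction of the test was up but the median below 0 for detoxification of reactive oxygen (-0.02) and aryl hydrocarbon receptor targets (-0.04). It was up with a mean below 0 for endoplasmic reticulum chaperones and cholesterol biosynthesis (-0.02 each), and down with a mean above 0 for immediate early genes (0.02) and nuclear-retained RNAs (0.19).

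With 3 libraries per group there are 10 splits of the libraries, and the share of splits as large as the real one cannot fall under 0.1, so the splits are too few to decide on chance. The real split, 1 of the 10 to reach its size for each result, called 5540 genes, 2580 higher and 2960 lower, and 571 at least 2-fold changed, while the highest of the others was 0 for each. For lists past camera with the preset correlation the real split gave 15 and the others from 4 to 9, although those splits called 0 genes. Each other split mixes both groups on each side. The group difference then adds to its spread, and part of it stays between the sides. Neither the 0 genes nor the lists of those splits therefore show what libraries without a group difference would give.

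The rise of stress response genes may follow the transcription factor ATF4, whose known targets include part of the tRNA synthetases. Grouped from general knowledge, and leaving out members of the fixed lists, 10 synthetase genes linked to ATF4 had a mean log2 fold change of 0.40 ± 0.23 (SD over genes), and 10 of them rose. The 8 other cytosolic synthetase genes had a mean of -0.13 ± 0.18 (SD over genes), of which 0 rose and 3 fell. The difference of the means was 0.53 (exact two-sided permutation p over genes = 4.6e-05), although genes are not independent replicates. LARS1 in the first group and HARS1 and QARS1 in the second lie in shifted chromosome blocks, for which copy number is open. Without them, a choice made after seeing the data, the difference was 0.55 between 9 and 6 genes (exact two-sided permutation p over genes = 2.0e-04). CARS1 and GARS1 (0.92 and 0.56) in the first group and VARS1 and QARS1 (-0.36 each) in the second were picked for mention after their values were seen. This is consistent with an ATF4 response, although the ATF4 protein was not measured.

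DHRS3, STRA6 and ALDH1A3, genes of retinoid handling of which STRA6 was picked after its value was seen, were higher by 2.41, 1.61 and 0.89 on the log2 scale. ALDH1A3 lies in a higher block of chromosome 15, and 27.5% of its exon bases overlap ALDH1A3-AS1 on the opposite strand, itself higher by 1.00. A hypothesis that retinoid genes rise more widely was not borne out. Of 10 other measured members of a retinoid list 1 rose (RBP1, 1.20 ± 0.43, SE) and 5 fell, with TGM2 and CRABP2 at -1.14 and -0.58. One of the genes that fell, NRIP1, also belongs to the fixed list of estrogen response genes, so it was not unseen.

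The level of XIST rose 13.1-fold while genes on the X chromosome as a whole stayed near the autosomes. The median log2 fold change was -0.02 over 383 X-linked genes and -0.01 over autosomal genes, a difference of -0.01 that was not tested.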
